A study of Mus musculus with 16 samples.

How the data were processed

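RNA of 16 samples of sorted spleen CD8 T cells was measured on 1-colour Affymetrix arrays, in 4 groups of 4 samples: effector and memory cells from chimeric mice with Il4i1 knockout (KO) bone marrow or wild-type (WT) bone marrow. Per the labels' protocols, total RNA came from sorted cells with the RNeasy Micro Kit and 1 ng of it was amplified and biotin-labelled with the Affymetrix GeneChip WT Pico kit. The deposited table gives 1 value for each of 41345 probe sets in each sample. The deposited values were taken as log2 expression normalized by the authors. The log base and the normalization method are not given in the sources used here, and the base was inferred from the range of the values, 0.7365 to 14.0453, since a natural or decimal log of that range would pass what an array scanner records. The 16 array medians lay between 4.1169 and 4.2214, and the distributions were near equal without being identical. No background level or detection call came with the values, so the number of arrays is the only measure of precision.

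The probe table listed 25335 of the probe sets with gene symbols. Of these, 23521 carried exactly 1 symbol and were used, and 1814 carried several symbols and were left out of the gene tests, as were 16010 probe sets that the table does not list. Entrez gene IDs matched 23328 of the single-gene probe sets to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed through it. That table also gave the order of genes along chromosomes. For 1082 genes with several probe sets, the one with the highest mean over all arrays was taken, which left 22180 genes. No filter on dim probe sets was applied in the values reported, and a gene whose signal lies under the median of most arrays is named with the number of arrays above their own median.

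limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 16 arrays together, with 12 residual degrees of freedom and a prior of 4.23 (lmFit, contrasts.fit, eBayes). The 5 comparisons were KO against WT in effector cells, KO against WT in memory cells, the difference between these (interaction, effector minus memory), KO against WT averaged over both subsets, and effector against memory averaged over both genotypes. Benjamini-Hochberg adjustment ran over all genes within a comparison, and a gene passed at an adjusted p under 0.05, two-sided. Errors of genes are standard errors (SE) from this fit. The labels do not say whether the samples of a group are separate animals, so p-values measure the spread between samples. The targeted gene and the sort genes also had exact two-sided permutation tests of the difference in means; the smallest p that 4 arrays against 4 can reach is 0.0286, and for effector against memory, with 4900 arrangements within genotype, 0.000408.

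Gene lists, 22 in number, were written before the data were examined, as were the comparisons, the tests, the rule for naming genes and the alternatives listed last, except 1 named there. The tests of the place of genes on chromosomes, and those the closing section names so, were chosen after the results were seen. The gene lists cover T cell programmes, the AHR and amino acid deprivation responses that the enzyme made by Il4i1 can touch, and markers of other spleen cells. Each was tested against all other genes with camera of limma, with the correlation between genes preset at 0.01 and Benjamini-Hochberg adjustment over the 22 lists. Camera with an estimated correlation and the rotation test fry were run beside it. Fry asks whether the genes of a list move on balance one way and sets the list against no other genes. Means of lists carry the standard error over arrays, and the exact permutation p of a list mean stands beside some. A count adjusted over the list alone uses Benjamini-Hochberg over the members of that list only.

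Genes were named by a fixed rule. Per comparison, the rule takes the 10 largest rises and 10 largest falls among genes that passed and whose groups did not overlap, filled to 5 per direction with the smallest p where fewer passed. It adds Il4i1, Il7r, Cd44, Cd8a, Cd8b1 and up to 4 members of each list with the smallest p, from which the text draws its examples. Predicted genes and RIKEN clones were counted and not named, and genes named outside the rule are marked as chosen after their values were seen.

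The pipeline was tested on simulated data made from the real means and spreads of the genes, drawn independently of each other, in which 67, 67 and 66 of 22180 genes were changed by 0.5, 1 and 2 on the log2 scale. In effector KO against WT, 32.8%, 83.6% and 100% of them were called, and in memory KO against WT 41.8%, 83.6% and 98.5%. The shares were 10.4%, 74.6% and 98.5% for the interaction, 59.7%, 98.5% and 100% for KO against WT over both subsets, and 70.1%, 97% and 100% for effector against memory. Of the unchanged genes, 6, 6, 7, 12 and 9 were called in the 5 comparisons in this order. The cell cycle list, simulated in memory KO against WT, was not called at a fall of 0 and was called when its genes fell by 0.25 and when they fell by 0.5.

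Alternatives were filters that kept genes above the array median or 25th percentile on at least 4 arrays, quantile normalization, centring of each array on its median, a fit of only the 8 arrays of a comparison, eBayes with trend and robust, array weights, the mean of all probe sets of a gene, all 41345 probe sets one by one, the replicate number as a fixed or random block, effector against memory within each genotype, and leaving out each of the 16 arrays. A fit without the genes on the chromosome that carries Il4i1 was chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.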

Results

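The mice had received wild-type (WT) or Il4i1 knockout (KO) bone marrow and then leukaemia cells of the Eµ-TCL1 model, a mouse model of chronic lymphocytic leukaemia (CLL). Il4i1 encodes a secreted amino acid oxidase that acts on phenylalanine, tyrosine and tryptophan. Spleen CD8 T cells were sorted 5 weeks after the leukaemia transplantation into effector cells (CD44 positive, CD127 negative) and memory cells (CD44 high, CD127 high). All mice were female, and expression was measured on arrays. The 4 groups, effector KO, effector WT, memory KO and memory WT, hold 4 samples each, and 22180 genes were tested. Values are log2 expression, and a log2 fold change is KO minus WT or effector minus memory. Array effector KO 4 stood apart from the other 15, with correlations over genes of 0.939 to 0.948 to them, while all other pairs lay between 0.961 and 0.987.

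Expression of the targeted gene cannot check the genotype labels here. The probe set that covers Il4i1 is shared with Nup62, a nuclear pore gene, and Il4i1b, so its signal does not belong to Il4i1 alone. Its mean was 5.90 in effector KO (SD 0.11, n = 4) and 5.95 in effector WT (SD 0.06, n = 4), with an exact permutation p of 0.6286. In memory cells it was 5.67 in KO (SD 0.14, n = 4) and 5.99 in WT (SD 0.06, n = 4). This difference of -0.33 has an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and an adjusted p of 0.305 over all genes. The genes of the CD8 coreceptor, Cd8a and Cd8b1, differed between KO and WT by -0.23 and 0.00 in effector cells and by 0.03 and 0.16 in memory cells, none past the threshold. Cd44, a sort marker, differed by -0.28 in effector cells (adjusted p = 0.518) and by -0.06 in memory cells (adjusted p = 0.901).

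The comparison of effector KO with effector WT asks what the loss of Il4i1 in bone marrow derived cells does to effector CD8 T cells in leukaemia-bearing mice. Klk1b22, a kallikrein-family serine protease, was 66.1-fold higher in KO (log2 fold change 6.05 ± 0.27 SE, n = 4 and 4, adjusted p = 2.34e-09), with means of 8.72 and 2.67. Its WT signal lay under the array median on all 8 WT arrays, and no background level came with the values, so the size of its fold is uncertain and can be larger. Il7r, the interleukin-7 receptor chain that carries the sort marker CD127, rose 3.14-fold (1.65 ± 0.25, adjusted p = 0.0183), from 4.04 to 5.69, against 10.71 or more in the memory groups. Its effector WT signal lay under the array median on 3 of 4 arrays, so the size of this fold is uncertain too. The effector gate was CD127 negative, so Il7r is a gate gene in this comparison. Whether the purity of the effector sort plays a part in its rise was not tested. Igsf23, of the immunoglobulin superfamily, rose 3.57-fold (1.84 ± 0.22, adjusted p = 0.0023). Tbc1d17, whose product acts on Rab GTPases of membrane traffic, fell 2.45-fold (-1.29 ± 0.19, adjusted p = 0.0117). In all, 12 genes passed, 8 higher and 4 lower in KO. Of these, 7 changed at least 2-fold and 1 is a predicted gene.

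The other genes that rose in effector KO were Ubxn11 (1.16 ± 0.17, adjusted p = 0.0117), Myadm, a myeloid-associated membrane protein gene (1.13 ± 0.15, adjusted p = 0.00497), Smim40 (0.92 ± 0.13), Lamp1 and Wdtc1. Lamp1 encodes the lysosomal membrane protein that appears on the surface of cytotoxic cells on degranulation, and it rose by 0.72 ± 0.11 (adjusted p = 0.0199). Wdtc1 rose by 0.70 ± 0.08 (adjusted p = 0.00184). Alkbh6, of the AlkB dioxygenase family, fell by 0.64 (SE 0.11, adjusted p = 0.0422), and Ndufa3, a subunit of respiratory complex I, fell by 0.49 (SE 0.08, adjusted p = 0.0383). Emc10, of the endoplasmic reticulum membrane protein complex, was at -0.53 ± 0.09 and missed the threshold (adjusted p = 0.0525). Of the 12 genes, 7 lie on the chromosome that carries Il4i1, which holds 8.85% of the tested genes (Fisher's exact p = 2.23e-05). Klk1b22, Igsf23, Myadm, Tbc1d17, Alkbh6 and Ndufa3 are among them.

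Memory and stem-like genes were higher as a list in effector KO. Of 22 measured members, 18 were higher, Il7r passed over all genes, and 8 rose and 1 fell adjusted over the list alone. The mean of the list was 0.41 ± 0.11 (SE over arrays, camera adjusted p = 1.46e-06, adjusted p = 0.12 with an estimated correlation). The gate gene Il7r is a member of this list, and the mean, counts and tests include it. Besides Il7r, the migration receptor S1pr1 was at 1.09 ± 0.21 (adjusted p = 0.119). The transcription regulator Id3 was at 0.99 ± 0.19 (adjusted p = 0.119) and Klf2, which governs trafficking genes, at 1.07 ± 0.24 (adjusted p = 0.258). Their effector KO means of 8.74, 4.73 and 6.96 lay between those of effector WT (7.65, 3.75 and 5.89) and memory WT (9.67, 5.6 and 7.28). Whether the purity of the effector sort plays a part in the rise of the list was not tested. Inhibitory receptor and exhaustion genes were lower in 20 of 23, with 0 past the threshold over all genes and 2 lower adjusted over the list alone. Their mean was -0.43 ± 0.19 (adjusted p = 5.67e-06, adjusted p = 0.376 with an estimated correlation). Cd200r1, an inhibitory receptor, was at -1.48 ± 0.32 (adjusted p = 0.242) and Cd244a at -1.81 ± 0.51 (adjusted p = 0.385). On array effector KO 4 this list had a mean of 7.68, while the other effector KO arrays lay between 8.06 and 8.58 and the effector WT arrays between 8.54 and 8.65.

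Type I interferon response genes were higher in 27 of 31, with 0 past the threshold over all genes and 9 higher adjusted over the list alone. Here the mean was 0.35 ± 0.13 (adjusted p = 3.41e-07, adjusted p = 0.388 with an estimated correlation). The expression of the list was 7.35 on array effector KO 4 and 6.89 to 7.07 on the other effector KO arrays. Examples are Irf7, the interferon regulatory factor of this response, at 0.84 ± 0.27 and the ubiquitin-like modifier Isg15 at 0.73 ± 0.23, each with an adjusted p of 0.442. The T cell receptor and immediate early list was higher in 18 of 25 (2 higher adjusted over the list alone, mean 0.23 ± 0.10, adjusted p = 0.00849, adjusted p = 0.376 with an estimated correlation). The activation marker Cd69 was at 0.72 ± 0.17 (adjusted p = 0.285). Without effector KO 1 or effector WT 2 the adjusted p of this list was 0.116 or 0.0639. Heat shock genes were higher in 12 of 16 (0 adjusted over the list alone, mean 0.21 ± 0.09, adjusted p = 0.00854, adjusted p = 0.376 with an estimated correlation). Without effector KO 1 that list had an adjusted p of 0.0918. Platelet markers were lower in 8 of 10, 2 of them adjusted over the list alone (mean -0.29 ± 0.15, adjusted p = 0.00352, adjusted p = 0.376 with an estimated correlation). Ppbp was at -0.84 ± 0.39. The adjusted p of the list was 0.103 without effector WT 4 (mean -0.16) and 0.0693 among genes above the array median (mean -0.26).

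No other list passed in effector cells. Cytotoxic genes were higher in 13 of 23 (mean 0.23 ± 0.10, adjusted p = 0.218), 0 of them past the threshold over all genes or adjusted over the list alone. The granzyme Gzma was at 1.75 ± 0.53 (adjusted p = 0.442) and the transcription factor Tbx21 at 0.77 ± 0.29. AHR targets are genes under the aryl hydrocarbon receptor, which Il4i1 products can activate. They were higher in 11 of 21 (median 0.04, mean -0.03 ± 0.04, test upward, adjusted p = 0.638), and 8 of the 21 lay above the array median in effector WT. The receptor gene Ahr itself was at -1.02 ± 0.29 (adjusted p = 0.385). The amino acid deprivation list of ATF4 was higher in 16 of 27 (mean 0.05 ± 0.03, adjusted p = 0.378), with Ddit3 at 0.61 ± 0.19. The mean was 0.11 ± 0.03 for the interferon gamma response (adjusted p = 0.102), -0.07 ± 0.17 for cell cycle genes (0.312) and -0.08 ± 0.11 for glycolysis (0.218). The sign of the last 2 rests on array effector KO 4, at 7.38 and 7.25. The other effector KO arrays lay at 7.82 to 8.14 and 7.62 to 7.74, and effector WT at 7.89 to 7.98 and 7.64 to 7.71. The mean was -0.01 ± 0.02 for oxidative phosphorylation (0.638), 0.15 ± 0.06 for chemokine receptors and adhesion (0.32) and 0.16 ± 0.06 for cytokine receptors (0.218). B and CLL cell markers were at 0.12 ± 0.06 (adjusted p = 0.265), myeloid markers at 0.03 ± 0.05 (0.749), CD4 and regulatory T cell markers at -0.15 ± 0.13 (0.638) and CD8 identity genes at 0.03 ± 0.05 (0.903). Median, mean and test differed in sign for ribosomal proteins (0.02, 0.01, downward, adjusted p = 0.903), NK cell markers (-0.01, 0.08, downward, 0.638) and erythroid markers (0.06, -0.04, downward, 0.903).

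Over the 16 fits that each left out 1 array, the number of genes passing in effector cells was 4 without effector WT 1, 6 without effector WT 2, 6 without effector WT 3 and 42 without effector KO 2, and it was 4 in a fit of the 8 effector arrays alone. The calls of Klk1b22, Igsf23, Myadm and Wdtc1 stood in each of these 16 fits. Those of Ndufa3, Alkbh6, Lamp1, Il7r, Smim40, Ubxn11 and Tbc1d17 were lost in 13, 12, 7, 4, 3, 3 and 2 of them, with a highest adjusted p of 0.17 for Ndufa3 and 0.0952 for Il7r.

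**Figure D1:**
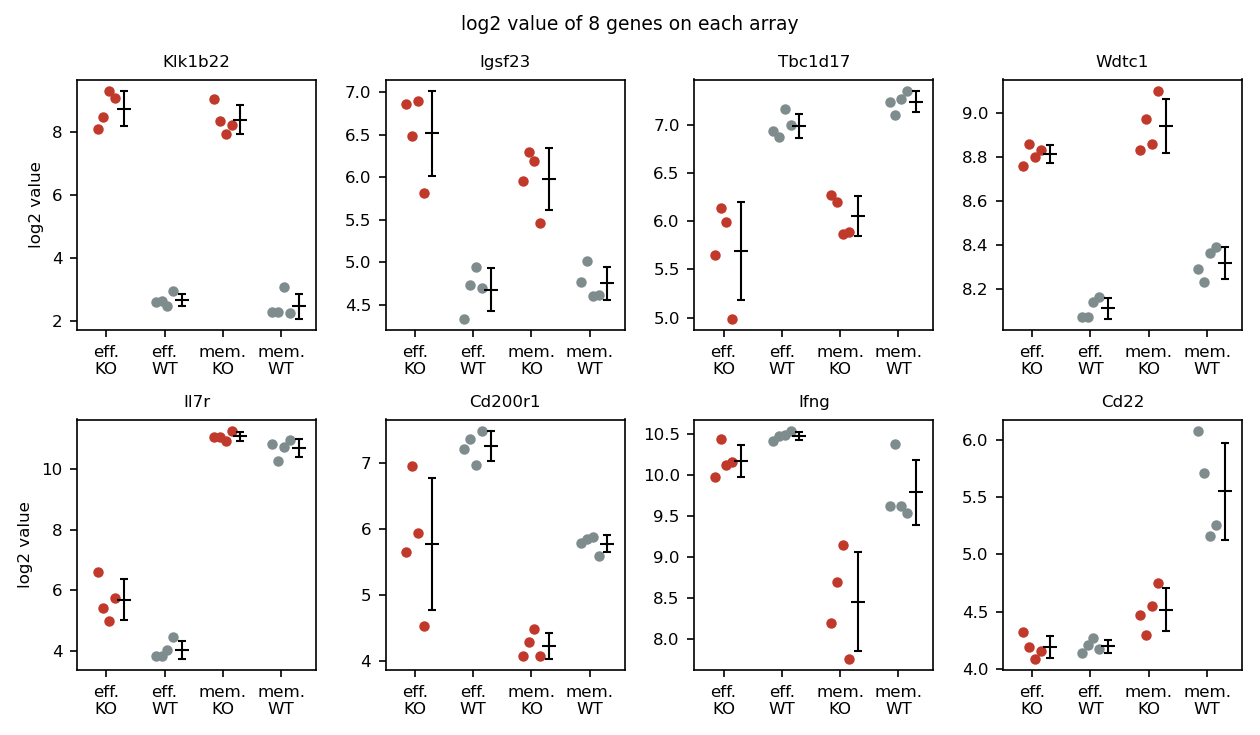
Log2 expression of Klk1b22, Igsf23, Tbc1d17, Wdtc1, Il7r, Cd200r1, Ifng and Cd22 in the 4 groups, with 1 point per array and the mean ± SD in black. Klk1b22 lay between 7.94 and 9.29 on the 8 KO arrays and between 2.26 and 3.07 on the 8 WT arrays.

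In memory cells, KO and WT differed in 25 genes, 8 higher and 17 lower in KO. At least 2-fold changes make up 15 of them, and 3 are predicted genes or RIKEN clones. Ifng, which encodes interferon gamma, fell 2.53-fold (-1.34 ± 0.24, n = 4 and 4, adjusted p = 0.0404), from 9.79 to 8.45, and the chemokine gene Ccl4 fell 1.75-fold (-0.81 ± 0.13, adjusted p = 0.0234). Klk1b22 was 59.8-fold higher (5.90 ± 0.27, adjusted p = 3.43e-09), again a fold of uncertain size over a dim WT signal of 2.48. Plaur, the urokinase receptor, rose 2.98-fold (1.58 ± 0.22, adjusted p = 0.00615), and Fbxo17, an F-box protein gene, rose 2.93-fold (1.55 ± 0.18, adjusted p = 0.00188).

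Among the other rises were Igsf23 (1.23 ± 0.22, adjusted p = 0.0452), the zinc finger gene Zfp128 (0.72 ± 0.11, adjusted p = 0.0145) and Wdtc1 (0.62 ± 0.08, adjusted p = 0.00311). Irgc1 rose by 1.31 ± 0.19 and Zfp946 by 0.86 ± 0.14, on signals that lay above the array median on 3 and 0 of the 16 arrays. Falls included Tnip3, an inhibitor of NF-kB signalling (-1.29 ± 0.22, adjusted p = 0.0334), the ribonuclease gene Rnase6 (-1.19 ± 0.22, adjusted p = 0.0479), Tbc1d17 (-1.18 ± 0.19, adjusted p = 0.0173) and Trerf1, a transcriptional regulator (-1.09 ± 0.14, adjusted p = 0.0025). Scd1, a fatty acid desaturase, fell by 1.26 (SE 0.23) and Adgre4, a myeloid adhesion receptor, fell by 1.13 (SE 0.20), above the array median on 3 and 5 arrays. Cd22, a receptor of B cells, fell by 1.04 (SE 0.16, adjusted p = 0.0145), from 5.55 to 4.52. Of the 25 genes, 12 lie on the chromosome of Il4i1 (Fisher's exact p = 3.88e-07), among them Klk1b22, Plaur, Fbxo17, Igsf23, Zfp128 and Tbc1d17. Il7r was at 0.38 ± 0.25 in memory cells and did not pass (adjusted p = 0.617).

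Inhibitory receptor and exhaustion genes were lower as a list in memory KO. Of 23 measured, 20 were lower, 0 past the threshold over all genes and 15 adjusted over the list alone. The mean was -0.91 ± 0.23 (camera adjusted p = 1.13e-18, exact permutation p of the list mean 0.0286, adjusted p = 0.0691 with an estimated correlation, fry adjusted p = 0.014). The checkpoint receptors Tigit (-1.73 ± 0.32, adjusted p = 0.052), Lag3 (-1.37 ± 0.28, adjusted p = 0.0754) and Havcr2 (-1.97 ± 0.41, adjusted p = 0.0797) lay close to the threshold. Cd200r1 was at -1.55 ± 0.32 (adjusted p = 0.0797). Cell cycle genes were lower in 45 of 45, again 0 over all genes and 36 adjusted over the list alone. For these the mean was -0.70 ± 0.31 (adjusted p = 4.09e-28, exact permutation p 0.0857, adjusted p = 0.159 with an estimated correlation). Examples are Hmmr, a mitotic spindle gene (-1.14 ± 0.28, adjusted p = 0.143), and the replication genes Gins2 (-0.86 ± 0.23) and Cdc45 (-0.86 ± 0.24). The memory KO arrays were spread in both lists. The inhibitory list mean was 6.63 and 6.64 on memory KO 1 and 4, 7.36 and 7.37 on memory KO 2 and 3, and 7.75 to 8.14 in WT. The cell cycle mean was 6.60 and 6.54 on memory KO 1 and 4, 7.29 and 7.82 on memory KO 2 and 3, and 7.60 to 7.85 in WT.

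B and CLL cell markers moved with these lists. They were lower in memory KO in 21 of 24, Cd22 past the threshold over all genes and 12 adjusted over the list alone. Their mean was -0.57 ± 0.19 (adjusted p = 6.33e-14, adjusted p = 0.0691 with an estimated correlation, fry adjusted p = 0.014). The B cell transcription factor Pax5 was at -1.09 ± 0.23 (adjusted p = 0.0797) and Ms4a1, which encodes CD20, at -1.40 ± 0.30 (adjusted p = 0.0817), each above the array median on 6 arrays. The immunoglobulin heavy chain gene Ighm was at 0.24 ± 0.22 (adjusted p = 0.734), with means of 11.33 in KO and 11.09 in WT. CD4 and regulatory T cell markers were lower in 11 of 15, 4 adjusted over the list alone (mean -0.41 ± 0.16, adjusted p = 0.00129, adjusted p = 0.159 with an estimated correlation). Ctla4, which is also on the inhibitory list, was at -0.82 ± 0.23 and Ikzf2 at -1.41 ± 0.49. The lineage genes, picked after their values were seen, had means in KO and WT of 5.52 and 5.56 for Foxp3 and 4.28 and 4.67 for Cd4. Myeloid markers were lower in 21 of 30 (0 adjusted over the list alone, mean -0.20 ± 0.15, adjusted p = 0.00482, adjusted p = 0.372 with an estimated correlation), with Lyz2 at -0.80 ± 0.29. Without memory KO 1 or memory KO 4 the mean was -0.13 or -0.11 and the adjusted p 0.0754 or 0.0641. Platelet markers were lower in 9 of 10 (mean -0.25 ± 0.16, adjusted p = 0.0371, adjusted p = 0.431 with an estimated correlation). This call was lost without memory KO 1 (0.289), memory KO 3 (0.0552), memory WT 3 (0.203) or memory WT 4 (0.0735) and among genes above the array median (0.098). CD8 identity genes did not pass (median 0.00, mean 0.02 ± 0.04, test downward, adjusted p = 0.864).

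Type I interferon genes were higher in memory KO in 30 of 31, 0 over all genes and 12 adjusted over the list alone. The interferon mean was 0.45 ± 0.18 (adjusted p = 4.73e-12, exact permutation p 0.0857, adjusted p = 0.159 with an estimated correlation). The antiviral synthetase Oas2 was at 0.98 ± 0.26 (adjusted p = 0.185), Cmpk2 at 0.97 ± 0.26 (adjusted p = 0.176) and Usp18, a brake on interferon signalling, at 0.80 ± 0.23 (adjusted p = 0.216). The list mean was 7.86 and 7.93 on memory KO 1 and 4, 7.44 and 7.34 on memory KO 2 and 3, and 6.94 to 7.48 in WT. Memory and stem-like genes were higher in 16 of 22 (0 adjusted over the list alone, mean 0.25 ± 0.09, adjusted p = 0.00195, adjusted p = 0.159 with an estimated correlation). The transcription factor Lef1 was at 0.41 ± 0.13 and Il6ra at 0.97 ± 0.31. Cytotoxic genes were lower in 13 of 23, Ifng and Ccl4 past the threshold and 5 lower adjusted over the list alone (mean -0.15 ± 0.07, adjusted p = 0.00739, adjusted p = 0.159 with an estimated correlation, fry adjusted p = 0.0587). The other members did not fall, so the list did not move as a whole. Among them, chosen after their values were seen, Tbx21 had means of 8.78 in KO and 8.19 in WT, Gzmm 8.49 and 7.91, and Gzma 9.18 and 8.72. The chemokine Ccl3 was at -1.74 ± 0.36 (adjusted p = 0.0754) and Prdm1, which encodes Blimp-1, at -0.91 ± 0.20 (adjusted p = 0.0887).

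Glycolysis genes were lower in 19 of 23 (mean -0.20 ± 0.11, adjusted p = 0.000125, adjusted p = 0.372 with an estimated correlation), with Tpi1 at -0.82 ± 0.27. Oxidative phosphorylation genes were lower in 40 of 46 (mean -0.09 ± 0.05, adjusted p = 3.75e-05, adjusted p = 0.372 with an estimated correlation), with Cox5b at -0.30 ± 0.08. Neither list had a member past the threshold over all genes or adjusted over the list alone. The interferon gamma response did not pass in memory cells (mean 0.12 ± 0.09, 2 higher adjusted over the list alone, adjusted p = 0.0774). Nor did ribosomal proteins (0.06 ± 0.06, 0.0694), cytokine receptors (0.13 ± 0.07, 0.261), chemokine receptors (0.06 ± 0.05, 0.951), heat shock genes (0.18 ± 0.16, 0.524) or erythroid markers (0.03 ± 0.16, 0.704). Median, mean and test differed in sign for T cell receptor genes (0.04, 0.02, downward, adjusted p = 0.993), AHR targets (0.07, -0.09 ± 0.11, downward, 0.993), the amino acid deprivation list (0.04, 0.00 ± 0.04, downward, 0.993) and NK cell markers (-0.02, 0.07 ± 0.09, downward, 0.951). Ahr was at -0.70 ± 0.29 (adjusted p = 0.368) and Asns, the asparagine synthetase induced by amino acid shortage, at -0.47 ± 0.22 (adjusted p = 0.429).

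The number of genes passing in memory cells was 249 without memory KO 3, 92 without effector KO 4, 16 without effector WT 1, 15 without effector KO 3 or effector WT 3, 14 without memory WT 3, 13 without memory KO 1 or memory WT 1, 12 without memory WT 2 and 11 without memory KO 4, and it was 7 in a fit of the 8 memory arrays. Without the genes on the chromosome of Il4i1, 3 genes passed, 1 higher and 2 lower. Ccl4 and Ifng, at unadjusted limma p of 1.37e-05 and 3.46e-05, would not be among them. Their calls thus depend on that chromosome's genes being in the adjustment. Calls of Klk1b22, Plaur, Fbxo17, Irgc1, Wdtc1 and Trerf1 stood in all 16 fits without 1 array. Those of Scd1, Igsf23, Rnase6, Ifng, Tnip3, Adgre4, Ccl4, Tbc1d17, Zfp128, Zfp946 and Cd22 were lost in 13, 12, 12, 11, 8, 7, 5, 3, 3, 3 and 2, with a highest adjusted p of 0.146 for Ifng (without memory KO 1), 0.104 for Ccl4 (without memory KO 4) and 0.071 for Cd22 (without memory WT 2).

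Whether the knockout acted differently in effector and memory cells was tested as the interaction, effector minus memory. By limma, 0 genes passed, 1296 genes had an unadjusted p under 0.05, and the smallest adjusted p was 0.3, shared by Ankmy2 (-0.77 ± 0.13, n = 4 per group). The next were Scd1 (1.60 ± 0.33), Cd22 (1.03 ± 0.23), Ccl4 (0.86 ± 0.19), Zfp41 (0.74 ± 0.15), Plaur (-1.46 ± 0.31), Irgc1 (-1.26 ± 0.27), the glycogen synthase Gys1 (-0.89 ± 0.19) and Dact2 (-0.58 ± 0.12), each with an adjusted p of 0.62. Il7r had an interaction of 1.27 ± 0.36 (adjusted p = 0.837), Ifng 1.03 ± 0.33 (0.841) and Lag3 1.16 ± 0.40 (0.841). Genes called in 1 subset alone were thus not shown to differ between subsets. Of the 16 fits that left out 1 array, 15 gave 0 genes, and without memory KO 3 the number was 5.

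By camera, 8 lists differed between subsets, all with a more positive KO effect in effector cells. Of these fry called 2, and camera with an estimated correlation called 0. B and CLL cell markers had a positive interaction in 21 of 24 (mean 0.69 ± 0.20, 11 adjusted over the list alone, adjusted p = 3.51e-14, adjusted p = 0.0687 with an estimated correlation, fry adjusted p = 0.0414). Fcmr, the IgM receptor, was at 1.89 ± 0.50 (adjusted p = 0.837). In effector WT only 11 of the 24 markers lay above the array median. The rest had little room to fall there, so a fall in memory cells alone would make their interaction positive. Cytotoxic genes were positive in 20 of 23 (mean 0.38 ± 0.12, 1 adjusted over the list alone, adjusted p = 0.00016, adjusted p = 0.0687 with an estimated correlation, fry adjusted p = 0.0414), with Ccl3 at 1.57 ± 0.51. Cell cycle genes were positive in 44 of 45 (mean 0.63 ± 0.35, adjusted p = 5.42e-17, adjusted p = 0.5 with an estimated correlation), with Hmmr at 1.08 ± 0.39. Inhibitory receptor genes were positive in 19 of 23 (mean 0.48 ± 0.30, adjusted p = 8.53e-05, adjusted p = 0.5 with an estimated correlation), with Tigit at 1.20 ± 0.46. In the 6 lists other than B markers and cytotoxic genes, 0 members passed over all genes or adjusted over the list alone.

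Among these were T cell receptor genes (20 of 25 positive, mean 0.21 ± 0.14, adjusted p = 0.0225, adjusted p = 0.5 with an estimated correlation), with Egr3 at 0.77 ± 0.30. This call was lost without effector KO 1 (0.19), effector WT 2 (0.111), memory KO 2 (0.0642), memory WT 1 (0.0549) or memory WT 4 (0.128). Oxidative phosphorylation (38 of 46, mean 0.08 ± 0.06, adjusted p = 0.00565, adjusted p = 0.684 with an estimated correlation) was lost without memory KO 1 (0.113). Myeloid markers (22 of 30, mean 0.23 ± 0.16, adjusted p = 0.00941, adjusted p = 0.547 with an estimated correlation) were lost without effector WT 2 (0.054), memory KO 1 (0.113) or memory KO 4 (0.106). CD4 and regulatory T cell markers (10 of 15, mean 0.26 ± 0.21, adjusted p = 0.0419, adjusted p = 0.5 with an estimated correlation) were lost without any 1 of effector KO 1, 2 and 3, effector WT 2, 3 and 4, memory KO 1 and 4 and memory WT 1 (0.0527 to 0.158). The number of lists called was 5 without effector WT 2 and 5 without memory KO 1. No difference between subsets was called for memory and stem-like genes (mean 0.16 ± 0.14, adjusted p = 0.148), type I interferon (-0.10 ± 0.22, 0.211) or interferon gamma (-0.02 ± 0.09, 0.92). The same holds for AHR targets (0.06 ± 0.12, 0.678), amino acid deprivation (0.05 ± 0.05, 0.469), glycolysis (0.12 ± 0.16, 0.0641), ribosomal proteins (-0.05 ± 0.06, 0.148), chemokine receptors (0.09 ± 0.08, 0.469) and cytokine receptors (0.03 ± 0.09, 0.799). Nor was a difference called for CD8 identity (0.02 ± 0.06, 0.678), erythroid markers (-0.07 ± 0.19, 0.606), platelet markers (-0.04 ± 0.22, 0.542), heat shock genes (0.03 ± 0.18, 0.148) or NK cell markers (median -0.14, mean 0.01 ± 0.12, test downward, 0.764).

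Averaged over both subsets, KO differed from WT in 43 genes, 18 higher and 25 lower. Of the 43, 14 changed at least 2-fold and 3 are predicted genes or RIKEN clones. Cd200r1, which restrains immune cells that bind CD200, fell 2.86-fold (-1.52 ± 0.23, n = 8 and 8 arrays, adjusted p = 0.00741). Il7r rose by 1.02 ± 0.18 (adjusted p = 0.0265) and S1pr1 1.72-fold (0.78 ± 0.15, adjusted p = 0.048). Pvr, which encodes CD155, a ligand of TIGIT, fell 2.22-fold (-1.15 ± 0.18, adjusted p = 0.00941). Klk1b22 was 62.9-fold higher (5.97 ± 0.19, adjusted p = 1.15e-11), a fold of uncertain size over dim WT signals. The 23 other kallikrein genes tested lay between -0.33 (Klk1b9, above the array median on 4 arrays) and 0.45 (Klk8), both named after their values were seen, and none passed the threshold. Copies of this family are nearly alike in sequence, so which of them the probes read is uncertain.

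Further rises over both subsets were Igsf23 (1.53 ± 0.16, adjusted p = 0.000182), Fbxo17 (1.14 ± 0.13, adjusted p = 0.000404), Ubxn11 (1.02 ± 0.12, adjusted p = 0.000552) and Wdtc1 (0.66 ± 0.06, adjusted p = 3.23e-05). So did the calmodulin-dependent kinase gene Camk2b (0.67 ± 0.10, adjusted p = 0.0089, above the array median on 7 arrays), Adgrb2 (0.42 ± 0.08) and Taf1d (0.42 ± 0.08). Tbc1d17 (-1.24 ± 0.13, adjusted p = 0.000262), Pop4, a subunit of RNase P (-1.07 ± 0.15, adjusted p = 0.00441), Alkbh6 (-0.78 ± 0.08, adjusted p = 0.000155), Emc10 (-0.49 ± 0.07, adjusted p = 0.00194) and Ndufa3 (-0.40 ± 0.06, adjusted p = 0.00453) fell. In tests chosen after the calls were seen, here and in each subset above, genes were counted per chromosome. On the chromosome that carries Il4i1 lie 20 of the 43 genes, 6 higher and 14 lower, against 1959 of 22139 tested genes with a position in GRCm38.p6 (odds ratio 9.04, Fisher's exact p = 1.03e-10). They include Klk1b22, Igsf23, Fbxo17, Tbc1d17, Pvr, Pop4, Alkbh6, Emc10 and Ndufa3. Cd200r1, Il7r, S1pr1, Ubxn11 and Wdtc1 lie on other chromosomes. The next highest count was on chromosome 4, with 7 genes passing among 1279 tested. Its Fisher's exact p was 0.011, and 0.126 adjusted over the chromosomes.

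**Figure D2:**
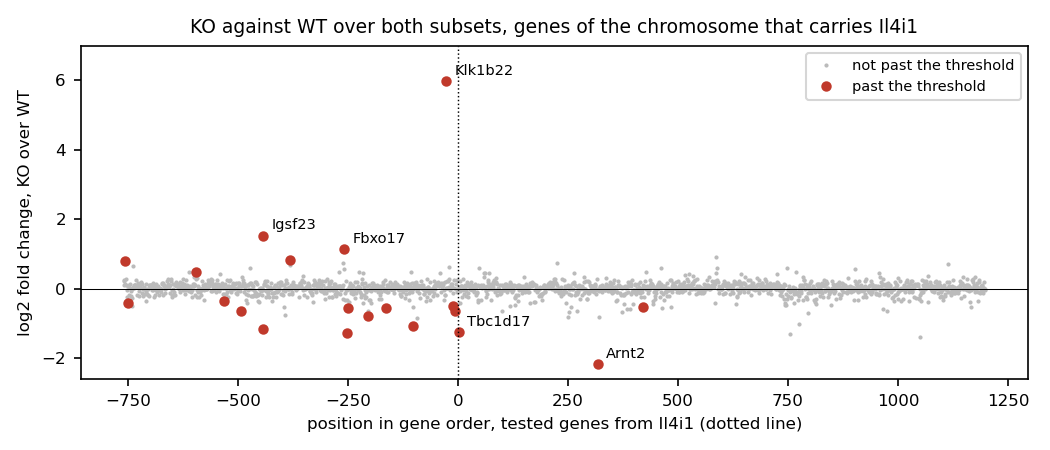
Log2 fold change, KO over WT, of each tested gene on the chromosome that carries Il4i1, plotted by its place in gene order counted from Il4i1, with genes past the threshold in red. Of the 20 red genes, 17 lie before Il4i1 and 3 after it, and Klk1b22 stands at 5.97.

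Inhibitory receptor and exhaustion genes were lower over both subsets in 22 of 23, Cd200r1 past the threshold over all genes and 17 adjusted over the list alone. The inhibitory mean was -0.67 ± 0.15 (adjusted p = 1.09e-16, adjusted p = 0.0718 with an estimated correlation, fry adjusted p = 0.00775). Tigit (-1.13 ± 0.23), Cd244a (-1.76 ± 0.36) and Havcr2 (-1.38 ± 0.29) each had an adjusted p of 0.0549. Memory and stem-like genes were higher in 17 of 22, Il7r and S1pr1 past the threshold, with 12 higher and 1 lower adjusted over the list alone. The memory list mean, with the gate gene Il7r included, was 0.33 ± 0.07 (adjusted p = 7.18e-07, adjusted p = 0.0718 with an estimated correlation, fry adjusted p = 0.00586). Id3 was at 0.66 ± 0.14 (adjusted p = 0.0549) and Klf2 at 0.78 ± 0.17 (adjusted p = 0.0653). Type I interferon genes were higher in 29 of 31, 0 over all genes and 18 adjusted over the list alone (mean 0.40 ± 0.11, adjusted p = 4.37e-14, adjusted p = 0.24 with an estimated correlation, fry adjusted p = 0.0279). Phf11b was at 0.36 ± 0.07 (adjusted p = 0.0549) and Usp18 at 0.75 ± 0.17 (adjusted p = 0.0673).

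Cell cycle genes were lower over both subsets in 45 of 45, 0 past the threshold over all genes or adjusted over the list alone (mean -0.39 ± 0.18, adjusted p = 3.19e-16, adjusted p = 0.298 with an estimated correlation), with Mcm6 at -0.27 ± 0.09. B and CLL markers were lower beside them in 21 of 24, 3 adjusted over the list alone (mean -0.23 ± 0.10, adjusted p = 2.63e-05, adjusted p = 0.298 with an estimated correlation). Memory cells carry both averages: the means in effector and memory cells were -0.07 and -0.70 for the cell cycle list and 0.12 and -0.57 for the B and CLL markers, of which 15 of 24 were higher in effector KO. The sign of the -0.07 rests on array effector KO 4 (7.38), beside 7.82 to 8.14 on the other effector KO arrays. Glycolysis (16 of 23 lower, mean -0.14 ± 0.08, adjusted p = 0.000712, adjusted p = 0.386 with an estimated correlation) was lower too. So were platelet markers (10 of 10 lower, 2 adjusted over the list alone, mean -0.27 ± 0.11, adjusted p = 0.000916, adjusted p = 0.298 with an estimated correlation). Oxidative phosphorylation genes were lower in 33 of 46 (mean -0.05 ± 0.03, adjusted p = 0.00235, adjusted p = 0.498 with an estimated correlation), a call lost among genes above the array median (0.0621). CD4 and regulatory T cell markers were lower in 10 of 15, 5 adjusted over the list alone (mean -0.28 ± 0.10, adjusted p = 0.0176, adjusted p = 0.298 with an estimated correlation). Interferon gamma response genes were higher in 22 of 27 (mean 0.11 ± 0.05, adjusted p = 0.0209, adjusted p = 0.309 with an estimated correlation). Without memory KO 1 or memory KO 4 the adjusted p was 0.0654 or 0.0511 for the first and 0.094 or 0.0694 for the second. Heat shock genes were higher in 13 of 16, 1 adjusted over the list alone (mean 0.20 ± 0.09, adjusted p = 0.0275, adjusted p = 0.298 with an estimated correlation). That call was lost without effector KO 1, effector KO 3, effector WT 3, memory KO 1, memory KO 3, memory KO 4 or memory WT 3 (0.05 to 0.102).

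No call over both subsets was made for T cell receptor genes (mean 0.13 ± 0.07, adjusted p = 0.129, Cd69 at 0.59 ± 0.12), amino acid deprivation (0.03 ± 0.03, 0.621) or cytokine receptors (0.14 ± 0.05, 0.0932). Chemokine receptors (0.10 ± 0.04, 0.464), ribosomal proteins (0.03 ± 0.03, 0.274) and myeloid markers (-0.08 ± 0.08, 0.129) did not pass. Median, mean and test differed in sign for AHR targets (0.05, -0.06 ± 0.06, upward, adjusted p = 0.735, with 2 higher and 2 lower adjusted over the list alone), cytotoxic genes (-0.03, 0.04 ± 0.06, downward, 0.389), NK cell markers (-0.03, 0.08 ± 0.06, downward, 0.658), CD8 identity (0.01, 0.02 ± 0.03, downward, 0.814) and erythroid markers (0.10, -0.01 ± 0.10, upward, 0.727). Ifng was at -0.82 ± 0.17 (adjusted p = 0.0549), Ahr at -0.86 ± 0.20 (adjusted p = 0.0822) and the amino acid transporter Slc7a5 at 0.38 ± 0.11 (adjusted p = 0.134).

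**Figure D3:**
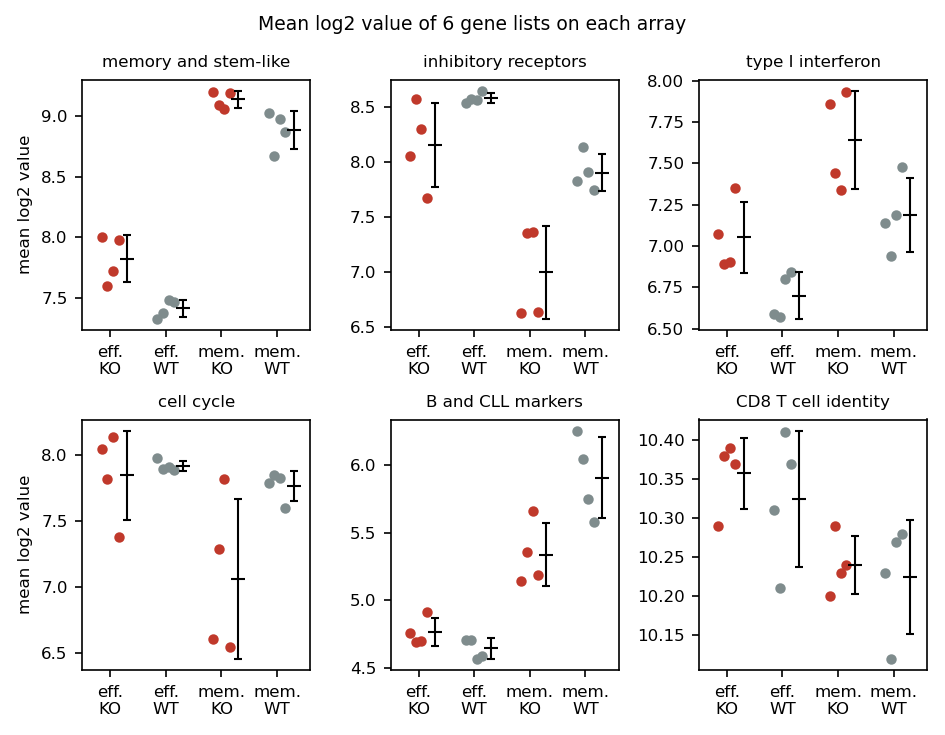
Mean log2 expression of 6 gene lists on each array, 1 point per array, in the 4 groups. The inhibitory receptor list lay between 6.63 and 7.37 on the memory KO arrays and between 7.75 and 8.14 on the memory WT arrays.

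The number of genes passing over both subsets was 329 without effector KO 2, 195 without memory KO 3, 28 without effector WT 4, 27 without memory KO 4, 26 without effector WT 1 and 23 without memory WT 1, 92 among genes above the array median, and 11 without the genes of the Il4i1 chromosome. Il7r and S1pr1, at unadjusted limma p of 3.33e-05 and 9.31e-05, would not be among the 11. With the replicate number as a fixed block it was 389 genes, 114 higher and 275 lower. Calls of S1pr1 and Taf1d were lost in 11 of the 16 fits without 1 array (highest adjusted p 0.115 and 0.0943) and those of Il7r and Adgrb2 in 7 (0.0696 and 0.0761). Cd200r1, Klk1b22, Igsf23, Wdtc1, Tbc1d17 and Pvr passed in all 16.

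Effector and memory cells, averaged over both genotypes, differed in 2696 genes, 1120 higher and 1576 lower in effector cells. At least 2-fold changes were seen in 304 of them (87 higher, 217 lower), and 173 are predicted genes or RIKEN clones. The sort genes moved with the gates. Il7r was 65.2-fold lower in effector cells (-6.03 ± 0.18, n = 8 and 8, adjusted p = 4.29e-12, exact permutation p = 0.000408), a fold of uncertain size over a dim effector signal, and Cd44 fell by 0.75 (SE 0.08, adjusted p = 1.99e-05). Apart from the sort genes, the largest falls in effector cells were Dapl1 (15.4-fold, -3.95 ± 0.16, adjusted p = 4.71e-10), the interleukin-6 receptor Il6ra (12.8-fold, -3.68 ± 0.22, adjusted p = 4.64e-08) and Treml2 (-2.93 ± 0.23, above the array median on 11 arrays). The lymph node homing receptor Ccr7 was 6.50-fold lower (-2.70 ± 0.16, adjusted p = 4.64e-08). The transcription factor Maf was 3.57-fold higher in effector cells (1.84 ± 0.28, adjusted p = 0.000364).

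Others higher in effector cells were Neb, which encodes the muscle protein nebulin (1.72 ± 0.14, adjusted p = 8.98e-07), Ceacam16 (1.55 ± 0.16), the integrin gene Itgad (1.51 ± 0.18, adjusted p = 3.19e-05), the inhibitory receptor Lilrb4a (1.33 ± 0.14, adjusted p = 1.23e-05) and Cstad (1.17 ± 0.13). Lower were Trim30c (-2.81 ± 0.25), Nt5e, which encodes CD73 (-2.75 ± 0.30, adjusted p = 1.71e-05), Tnfsf8, the CD30 ligand (-2.66 ± 0.20), the interleukin-12 receptor chain Il12rb2 (-2.47 ± 0.17, adjusted p = 2.34e-07) and Aff3 (-2.46 ± 0.17). Trim30c and Il12rb2 lay above the array median on 8 arrays each.

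Memory and stem-like genes were lower in effector cells in 19 of 22, with 16 falls and 2 rises over all genes and 16 and 3 adjusted over the list alone. Their mean was -1.39 ± 0.07 (adjusted p = 8.92e-20, adjusted p = 0.00136 with an estimated correlation). The gate gene Il7r (-6.03) is a member of this list and of the cytokine receptor list, and their means, counts and tests include it. Inhibitory receptor and exhaustion genes were higher in 23 of 23, 21 past the threshold over all genes and 23 adjusted over the list alone (mean 0.92 ± 0.15, adjusted p = 3.67e-19, adjusted p = 0.0242 with an estimated correlation). Among them were Lag3 (1.45 ± 0.20, adjusted p = 0.00013), Entpd1, which encodes CD39 (1.30 ± 0.18), Il10 (1.54 ± 0.23) and Cd200r1 (1.51 ± 0.23). Cytotoxic genes were higher in 16 of 23, with 11 rises and 3 falls over all genes and 12 and 3 adjusted over the list alone. The cytotoxic mean was 0.20 ± 0.06 (adjusted p = 0.000261, adjusted p = 0.0308 with an estimated correlation). Ccl4 (1.05 ± 0.09), the death ligand Fasl (0.92 ± 0.11) and Prdm1 (1.14 ± 0.14) rose, while the granzyme Gzmm fell by 2.11 (SE 0.27, adjusted p = 6.15e-05). Cell cycle genes were higher in 43 of 45, 16 over all genes and 29 adjusted over the list alone (mean 0.47 ± 0.18, adjusted p = 1.04e-12, adjusted p = 0.233 with an estimated correlation). The proliferation marker Mki67 was at 0.65 ± 0.16 and Tk1 at 0.77 ± 0.16. The cell cycle list mean was 7.92 in effector and 7.77 in memory cells of WT, and 7.85 and 7.07 of KO. Most of the averaged difference thus came from the memory KO arrays.

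Ribosomal protein genes were lower in effector cells in 49 of 56, 30 over all genes and, adjusted over the list alone, 39 lower and 2 higher (mean -0.25 ± 0.03, adjusted p = 4.8e-18, adjusted p = 0.0308 with an estimated correlation). Rps28 fell by 0.62 (SE 0.09). Cytokine receptors and STAT targets were lower in 17 of 26, with 12 falls and 3 rises over all genes and 15 and 6 adjusted over the list alone. For this list the mean was -0.73 ± 0.05 (adjusted p = 2.68e-06, adjusted p = 0.0135 with an estimated correlation), with Il4ra at -1.30 ± 0.11. Chemokine receptors and adhesion genes had 9 falls and 4 rises over all genes, and 10 and 6 adjusted over the list alone (23 measured, 14 lower, mean -0.38 ± 0.04, adjusted p = 0.00325, adjusted p = 0.0608 with an estimated correlation). S1pr1 (-1.71 ± 0.15), Itgb1 (-1.22 ± 0.11) and Itgae, the residency integrin CD103 (-1.32 ± 0.14), were lower. Type I interferon genes were lower in 24 of 31, 15 over all genes and, adjusted over the list alone, 18 lower and 1 higher (mean -0.54 ± 0.11, adjusted p = 1.51e-09, adjusted p = 0.157 with an estimated correlation). Oasl2 was at -2.16 ± 0.25 and Usp18 at -1.42 ± 0.17.

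Markers of B, myeloid, NK, erythroid and platelet cells were lower as lists in the effector sort. B and CLL cell markers were lower in 22 of 24, 19 over all genes and 19 adjusted over the list alone (mean -0.92 ± 0.10, adjusted p = 8.37e-20, adjusted p = 0.0135 with an estimated correlation). Ighm was at -1.97 ± 0.15 (adjusted p = 5.84e-07) and the MHC class II gene H2-Ab1 at -1.33 ± 0.11. Myeloid markers were lower in 27 of 30, with 15 falls and 1 rise over all genes and 18 and 1 adjusted over the list alone. The myeloid mean was -0.54 ± 0.08 (adjusted p = 6.83e-12, adjusted p = 0.0242 with an estimated correlation), with Fcer1g at -1.75 ± 0.10. NK cell markers were lower in 10 of 15 (5 falls and 1 rise over all genes, 5 and 2 adjusted over the list alone, mean -0.38 ± 0.06, adjusted p = 0.0189, adjusted p = 0.0522 with an estimated correlation). Erythroid markers were lower in 11 of 11 (2 over all genes and 2 adjusted over the list alone, mean -0.34 ± 0.10, adjusted p = 0.00726, adjusted p = 0.091 with an estimated correlation). Both lost their call among genes above the array median (0.0814 each). Platelet markers were lower in 9 of 10 (0 over all genes or adjusted over the list alone, mean -0.24 ± 0.11, adjusted p = 0.0207, adjusted p = 0.266 with an estimated correlation). They lost theirs without effector WT 2 (0.0674) or memory WT 3 (0.0504) and with that filter (0.109). CD8 identity genes were higher in 12 of 16, with 7 rises and 1 fall over all genes and 7 and 2 adjusted over the list alone. The identity mean was 0.11 ± 0.03 (adjusted p = 0.00541, adjusted p = 0.158 with an estimated correlation). The kinase gene Zap70 rose by 0.54 ± 0.06, and Cd8a was at 0.25 ± 0.07 (adjusted p = 0.0373, lost in 10 of 16 fits without 1 array).

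The remaining lists did not pass between effector and memory cells. T cell receptor genes had 3 rises and 5 falls over all genes, 6 and 7 adjusted over the list alone (mean -0.09 ± 0.07, adjusted p = 0.411), with Myc falling by 0.87 (SE 0.15). AHR targets had Il10, which is also on the inhibitory list, rising and Gpr15 at -1.88 ± 0.22, above the array median on 7 arrays, falling, the same count of 1 and 1 adjusted over the list alone (mean -0.07 ± 0.06, adjusted p = 0.309). The amino acid deprivation list had 4 falls, 4 falls and 1 rise adjusted over the list alone (mean -0.09 ± 0.03, adjusted p = 0.135). For the interferon gamma response the median was 0.05, the mean -0.22 ± 0.05 and the test downward (adjusted p = 0.308), with 4 rises and 8 falls over all genes, 5 and 8 adjusted over the list alone. The GTPases Iigp1 (-2.45 ± 0.17, adjusted p = 2.18e-07) and Igtp (-1.36 ± 0.14) fell. Glycolysis (median 0.01, mean -0.06 ± 0.08, test downward, adjusted p = 0.578, 1 rise and 2 falls), oxidative phosphorylation (-0.02 ± 0.03, 0.578, 1 fall) and heat shock genes (-0.26 ± 0.09, 0.051, 1 rise and 3 falls) did not pass either. Nor did CD4 and regulatory T cell markers (median -0.08, mean 0.01 ± 0.10, test downward, adjusted p = 0.539, 2 rises and 3 falls). The number of genes was 715 within WT alone and 1649 within KO alone.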

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

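None of the tests in this part was chosen after its result was seen, but the genes it covers are those named above. Dixon's test at 4 arrays was run within each group on 111 named genes and 22 list means, and 23 of 532 groups held a value past it. Chance flags about 1 in 20 groups, here 26.6, so their number is no larger than chance would give. The array memory WT 2 holds 7 of the 23: Ifng at 10.38 (other arrays of the group 9.54 to 9.62), Tigit at 10.45 (10.01 to 10.08), Cd244a at 8.72 (7.23 to 7.44), Ikzf2 at 8.48 (7.35 to 7.50), Mki67 at 10.16 (9.77 to 9.81), Lamp1 at 8.46 (8.68 to 8.72) and Ubxn11 at 4.70 (5.26 to 5.34). On memory WT 3 they are Klk1b22 at 3.07 (2.26 to 2.29), Klk1b9 at 3.57 and Gys1 at 6.32. On memory WT 4 they are Cdc45 at 6.90 (7.06 to 7.09) and the heat shock list at 7.38 (6.85 to 6.93), and on memory WT 1 Pvr at 5.92.

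Among the KO arrays, memory KO 4 had Il12rb2 at 5.45 (6.15 to 6.29), Phf11b at 10.34 and the ribosomal list at 8.98 (8.79 to 8.82), and memory KO 3 had Il10 at 5.49. On effector KO 4, the array that stands apart, Ikzf2 was at 5.63 (8.04 to 8.43) and the ribosomal list at 8.63 (8.56 to 8.57). On effector KO 1 the heat shock list was at 7.14 (6.87 to 6.88) and Plaur at 4.38, and on effector WT 1 Alkbh6 was at 6.86 and the cell cycle list at 7.98 (7.89 to 7.91).

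The KO effect differed between effector and memory cells by camera in 8 lists: cytotoxic (0.38), inhibitory receptors (0.48), T cell receptor (0.21), cell cycle (0.63), oxidative phosphorylation (0.08), B and CLL markers (0.69), myeloid markers (0.23) and CD4 and regulatory T cell markers (0.26). With an estimated correlation none of the 8 was called. Among 17824 probe sets left out of the gene tests, because they carry no gene or several, 3 passed in KO against WT over both subsets (1 higher, 2 lower). The highest, with no gene listed, was at 2.49 ± 0.22 (adjusted p = 0.000159).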

How the results depend on the processing

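The count without the genes of the chromosome that carries Il4i1 was chosen only after the results were seen. No other setting here was. No named call and no list call turned its direction under any setting. Over the other settings, 11 to 14 per comparison, the number of genes passing lay between 4 and 29 in effector KO against WT (12 as reported) and between 3 and 104 in memory KO against WT (25 as reported), and it was 0 in each for the interaction. It lay between 11 and 389 for KO against WT over both subsets (43 as reported) and between 715 and 3561 for effector against memory (2696 as reported).

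Counts that moved by over 1.5 times were as follows. A filter to genes above the array median gave 92 genes over both subsets (41 shared). Fits of only the 8 arrays of a subset gave 4 in effector cells (4 shared) and 7 in memory cells (5 shared), with fewer arrays to estimate the spread. Array weights gave 42 in memory cells (25 shared) and 72 over both subsets (42 shared). Tests of all probe sets gave 13 in memory cells and 26 over both subsets. Without the genes on the chromosome of Il4i1, 5, 3 and 11 passed in effector cells, memory cells and over both subsets, out of fewer genes, where 5, 13 and 23 of the reported calls lie elsewhere, so 0, 10 and 12 of those were lost as well. Effector against memory gave 715 within WT and 1649 within KO, from 8 arrays each. Except where fewer genes or arrays were used, the cause was not tested. Centring on the array median gave 18 higher and 45 lower over both subsets, and 7 and 25 in memory cells. Quantile normalization gave 24 and 28, and 7 and 12.

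The labels do not say that a replicate number marks a mouse, and not every pair correlated above 0.1, so the numbers are not taken to pair the samples, though the data hint at it within a genotype. Deviations from the group means correlated within a genotype by 0.02 to 0.24 between effector and memory arrays of the same number, 6 of 8 pairs over 0.1, and 7 of 8 pairs correlated best with their own number. Across genotypes the values were -0.03 to 0.14 between effector KO and effector WT. With the number as a replicate block, 29 genes passed in effector cells, 104 in memory cells and 389 over both subsets, holding all 12, 25 and 43 reported. As a random block within genotype, with a consensus correlation of 0.062, 13, 26 and 36 passed (12, 24 and 36 shared).

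Without 1 array, the number of genes ran from 4 (without effector WT 1) to 42 (without effector KO 2) in effector cells. In memory cells it ran from 11 (without memory KO 4) to 249 (without memory KO 3), and over both subsets from 23 (without memory WT 1) to 329 (without effector KO 2). For effector against memory it ran from 2144 (without memory WT 1) to 3221 (without effector KO 4). Without effector KO 4, the array that stands apart, 9, 92, 50 and 3221 genes passed in effector cells, memory cells, over both subsets and in effector against memory. The cause was not tested.

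Of the lists, camera with an estimated correlation called 0 in effector KO against WT, 0 in memory KO against WT, 0 in the interaction, 0 over both subsets and 7 in effector against memory, where the preset correlation called 6, 11, 8, 11 and 14. Fry called 1, 2, 2 and 3 in the first 4 of these. The number of lists in the interaction ran from 5 (without effector WT 2 or memory KO 1) to 11 (without effector KO 4).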

Other observations

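The genes of this paragraph lie outside the naming rule and were chosen only after their values were seen. Over both subsets, Arnt2, a partner of bHLH-PAS transcription factors, fell by 2.16 in KO (SE 0.39, n = 8 and 8, adjusted p = 0.029), and Slc1a5, a transporter of glutamine and other neutral amino acids, fell by 0.34 (SE 0.06, adjusted p = 0.032). Ech1, a peroxisomal and mitochondrial enoyl-CoA hydratase gene, fell by 0.55 (SE 0.06, adjusted p = 0.000492), and Pold1, a subunit of DNA polymerase delta, fell by 0.64 (SE 0.11, adjusted p = 0.0183). These 4 genes lie on the chromosome that carries Il4i1. On other chromosomes, Ifnar2, a chain of the type I interferon receptor, rose by 0.57, while the actin-linking gene Vcl fell by 0.44.

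The tests of place on the chromosome were all chosen after the result was seen, namely that 20 of the 43 genes passing over both subsets lie on the chromosome of Il4i1, for which Fisher's exact p = 1.03e-10 argues against chance placement. An effect of the edited gene on its direct neighbours is argued against for most of them, as 4 of the 20 lie within 50 tested genes of Il4i1; for these 4, Klk1b22 among them, it stays open. A hypothesis that stays open is DNA of another mouse strain kept around the knockout, which could change expression, or the match of the probes, at many genes along the chromosome. The distances do not settle it. The 20 genes lie nearer to Il4i1 than other tested genes of the chromosome (median 287 against 489 tested genes, one-sided permutation p = 0.0221 over 100000 draws). But 14 of the 20 lie over 200 tested genes away, and the permutation p is 0.0842 when genes are drawn per side. The calls also crowd on the shorter side: 17 lie before Il4i1 (761 tested genes) and 3 after it (1198, two-sided Fisher's exact p = 2.78e-05). Drawing per side takes this crowding out of the test. The crowding does not speak against kept DNA, which could reach further on that side. Strain sequences for the probes, or WT littermates that carry the same flanking DNA, would tell this from an effect of the enzyme. Cd200r1, Il7r and S1pr1 lie on other chromosomes, but 11 genes passed without the genes of the Il4i1 chromosome. Il7r and S1pr1, at unadjusted limma p of 3.33e-05 and 9.31e-05, would not be among them. Their calls over both subsets thus depend on that chromosome's genes being in the adjustment.

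For the lower cell cycle and inhibitory receptor lists in memory KO, the test of effector cells in the sort was planned for the cell cycle list, and the others, with the jackknife error, were chosen after the result was seen. One hypothesis is fewer B or CLL cells in the KO memory sort: the 21 B and CLL markers above the array median in memory WT had a median of -0.63 (SE 0.24), beside -0.76 ± 0.33 for the median of the cell cycle list and -0.82 ± 0.21 for that of the inhibitory list, and with the mean of the B markers as a covariate KO minus WT was -0.07 (SE 0.39) for the cell cycle list and -0.50 (SE 0.32) for the inhibitory list, errors too large to tell the lists apart, so it could play a part in either and stays open, although a CD8 gate would remove such cells and Ighm, at 11.33 in KO and 11.09 in WT, was not lower; 0 of the 24 markers are on another list and 11 lie above the array median in effector WT. A second is more effector cells in the WT memory sort, which is argued against as the sole cause of the cell cycle fall, since the share it needs (77.4%) would raise genes at least 4-fold higher in memory by 1.57 more than they rose (jackknife SE 0.69, 2.14 needed, 0.57 seen). For the inhibitory list that gap is 0.26 (SE 0.16, share 43.9%), which leaves it open, and 76 genes at least 2-fold higher in effector cells, outside both lists, had a median of -0.68 (SE 0.13) in memory KO (27 genes at -0.41, SE 0.12, when chosen in WT arrays alone), which fewer effector cells or a less effector-like state could each give. A change inside memory T cells, possibly toward a less activated state, remains another reading, and counts of dividing cells in the sort would help to tell them apart.

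For the higher type I interferon list in KO, no test was chosen after the result was seen. Without the array that stands apart (effector KO 4) the list kept a camera adjusted p of 1.3e-14 over both subsets. That value cannot speak against the array, since the list passed in memory cells alone and the correlation was preset. In effector cells the other KO arrays, at 6.89 to 7.07, still lay above the WT arrays, at 6.57 to 6.84. Whether the genes move together for a reason other than genotype, such as differing leukaemia load between mice, stays open, since the list has an adjusted p of 0.24 with an estimated correlation and memory KO 1 and 4 (7.86 and 7.93) lie above memory KO 2 and 3 (7.44 and 7.34). Tumour load of each mouse might settle this.

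None of the tests in this paragraph was chosen after its result was seen. Across genes, which are not independent replicates, KO effects in effector and memory cells correlated by 0.40, and by 0.39 without the chromosome of Il4i1, against at most 0.36 in 34 other joint splits of the arrays by number, so 1 of 35 reached it. No other split gave as many genes in effector KO against WT (12 against at most 2) or in memory KO against WT (25 against at most 10). The same held over both subsets (43 against at most 1) and in effector against memory (2696 against at most 80). The real grouping was thus 1 of 35 splits in each subset and 1 of 100 in the other 2, the least these tests can reach. This argues against chance without excluding it, and it does not tell what made the groups differ. For the interaction chance is not argued against, as 15 of 100 splits held as many genes at an unadjusted p under 0.05 (1296 against at most 2580).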
